A study of Homo sapiens with 27 samples.

How the data were processed

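RNA was measured by sequencing in HEK293 cells, an immortalized human embryonic kidney line. Per the labels, cells received a control siRNA (siCon), an siRNA against RUNX3 (siRUNX3) or an siRNA against YAP1 (siYAP1), were kept at low density, and went without serum for 1 h. They were then given TGFb1 at 1 ng/ml for 0, 15 or 120 min. The 9 combinations of siRNA and time hold 3 libraries each, 27 in all, and samples were grouped by these labels alone. The series calls the 3 libraries biological replicates, which the files cannot show; if they are repeat measurements of the same RNA, the adjusted p-values do not cover differences between cultures. The labels give no sequencing batch or date. No group was kept for 15 or 120 min without TGFb1, so a TGFb1 change here means the change from 0 min. It cannot be told apart from an effect of time or medium.

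The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments), 1 value per gene symbol for 24424 symbols in each library. Per the labels, the authors aligned trimmed reads to hg19 with TopHat and computed FPKM with Cufflinks, without stating versions. They also name a geometric normalization; the deposited FPKM totals differ between libraries, and whether that step was applied to the deposited values is not known. The files give no read counts, so the depth of each library is unknown and no interval for counting error was computed. Genes are identified by symbol because the files hold no coordinates.

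Values were analysed in R 4.3.3 with limma 3.58.1. The log2 of FPKM plus a pseudocount of 1 was modelled with a mean for each of the 9 groups, for 14543 genes with at least 1 FPKM in at least 3 libraries. Contrasts were tested with moderated statistics (eBayes with trend and robust settings), and p-values were adjusted by the Benjamini-Hochberg method within each contrast. A gene was called at an adjusted p under 0.05. The 16 planned contrasts compare 15 and 120 min with 0 min in each siRNA group, siRUNX3 and siYAP1 with siCon at each time, and the TGFb1 change of each with that of siCon (interaction). Another 7 contrasts were added after the values were seen, namely siRUNX3 against siYAP1 at each time, 120 against 15 min in siRUNX3 and in siYAP1, and the difference of the TGFb1 change between them at 15 and 120 min.

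The contrasts, the model, 25 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Of the lists, 24 had at least 5 tested genes and were tested with camera (limma) at a preset inter-gene correlation of 0.01, against all other tested genes; camera was also run with an estimated correlation. RUNX3 and YAP1 themselves were left out of the lists. The list of mitochondrially encoded mRNAs matched 0 symbols in the files. Apart from RUNX3 and YAP1, the rule names genes that passed the test, reached 1 FPKM on at least 1 side and had the 3 libraries of one group all above the 3 of the other. It takes the 12 largest rises and 8 largest falls at 120 min in siCon, 5 of each at 15 min, and 10 of each for siRUNX3 and siYAP1 that differed from siCon at all 3 times. It takes the 8 largest interactions of siRUNX3 and of siYAP1 at 120 min, and 2 to 4 members with the largest change from each list described. The same counts were applied to the siRUNX3 and siYAP1 time courses after their values were seen. Chance gives separated groups of 3 for 10% of genes.

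The alternatives tried were a pseudocount of 0.1, no filter on low values, quantile normalization, the replicate number as a block, a model with only the groups compared, and leaving out each library in turn. Alternatives added after the data were seen were a model without the 6 siCon libraries at 0 and 15 min, a correction that removes a smooth trend in transcript length and GC content from each library (14060 genes with GENCODE annotation), and quantile normalization before camera. The model was tested on simulated data built from the observed means and spreads of the siRUNX3 comparison of 15 with 0 min, with 14504 genes run. Of 50 genes changed 1.25-fold, 35 were called, of 50 changed 1.5-fold 47, and 50 of 50 were called at 2-fold and at 4-fold. Of 14304 unchanged genes, 7 were called.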

Results

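RNA levels were measured in 27 libraries of HEK293 cells, a human embryonic kidney line. Each of 9 groups, siCon, siRUNX3 and siYAP1 at 0, 15 and 120 min of TGFb1, held 3 libraries. RUNX3 is a transcription factor linked to TGFb signalling, and YAP1 is the transcriptional coactivator restrained by the Hippo pathway. TGFb1 is a secreted cytokine that acts through SMAD proteins. Group names give the labels of the libraries. Levels are FPKM as the mean ± SD of 3 libraries, log2 changes are given ± SE, and adjusted p-values are from limma with the Benjamini-Hochberg method. Read depth is unknown. Within groups, genes at 100 FPKM or more had a median coefficient of variation of 1.4% to 3.06% between the 3 libraries. The files do not show whether these come from separate cultures, and each adjusted p and count of called genes rests on this spread. The FPKM of a library summed to a group mean of 706377 in siCon at 0 min, 981956 at 15 min and 431114 at 120 min, and to between 590154 and 725177 in the siRUNX3 and siYAP1 groups.

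YAP1 transcript was higher in libraries labelled siYAP1 than in those labelled siCon at 0 and 15 min, and at 120 min its direction depended on the scaling. It stood at 13.1 ± 0.38, 11.1 ± 0.12 and 12.8 ± 0.6 FPKM at 0, 15 and 120 min in siYAP1, and at 4.01 ± 1, 2.87 ± 0.32 and 12.2 ± 0.46 FPKM in siCon. The log2 difference in YAP1 between siYAP1 and siCon was 1.51 ± 0.09 at 0 min, 1.65 ± 0.09 at 15 min and 0.06 ± 0.09 at 120 min, with limma adjusted p of 7.9e-14, 1.7e-14 and 0.54. After quantile normalization the difference at 120 min was -0.50, with a limma adjusted p of 2.1e-04. In siRUNX3, YAP1 stood at 13.8 ± 0.27, 11.5 ± 0.16 and 11.9 ± 0.18 FPKM, and differed from siCon at 120 min by -0.03 ± 0.09, and by -0.62 after quantile normalization. By these means YAP1 in siYAP1 was slightly lower than in siRUNX3 at 0 and 15 min and slightly higher at 120 min. The values thus show no clear reduction of YAP1 transcript particular to the libraries labelled siYAP1. RUNX3 had group means from 0.0202 to 0.207 FPKM and stayed under the minimum for testing, so a reduction by its siRNA was not detectable.

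**Figure D1:**
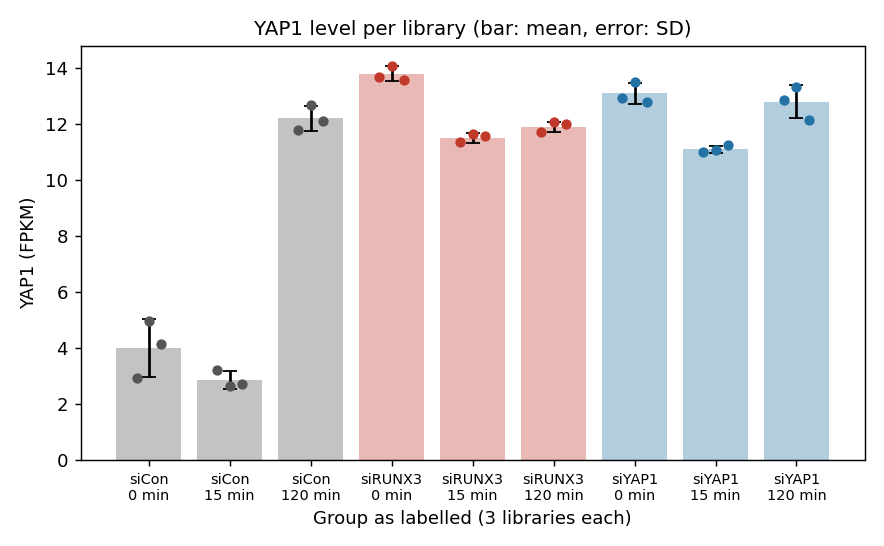
YAP1 level in FPKM (vertical axis, from 0) in the 9 groups as labelled. Points are single libraries, bars are group means and error bars are SD; the siYAP1 means lie between 11.1 and 13.1 FPKM and the siCon means between 2.87 and 12.2.

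The siCon libraries at 0 and 15 min stood apart from the other 21. Across the tested genes, siCon libraries at 0 min correlated with siRUNX3 and siYAP1 libraries at 0.708 to 0.746 (Pearson, log2 values), those at 15 min at 0.796 to 0.85, and those at 120 min at 0.954 to 0.972. The siRUNX3 and siYAP1 libraries of different groups correlated with each other at 0.966 to 0.991; genes are not independent replicates. To a smaller degree the siCon libraries at 120 min stood apart as well. On the third principal component of the log2 values (6.71% of variance) they lay between -59.09 and -57.41, and all other libraries between -5.204 and 19.03. Of 6279 genes with at least 10 FPKM in all 6 siRUNX3 and siYAP1 groups, 78 were listed at 0 in all 3 siCon libraries at 0 min, 6 at 15 min and 2 at 120 min. BCYRN1, a small noncoding RNA made by RNA polymerase III, was the most abundant symbol in the siCon libraries at 0 and 15 min. Among 20 markers of other cell types the highest group mean was 22.6 FPKM, for the alpha globin HBA1 in siCon at 15 min. The lysozyme gene LYZ stood at 13.1 ± 1 FPKM in siCon at 0 min and at or under 0.27 FPKM in the siRUNX3 and siYAP1 groups.

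**Figure D2:**
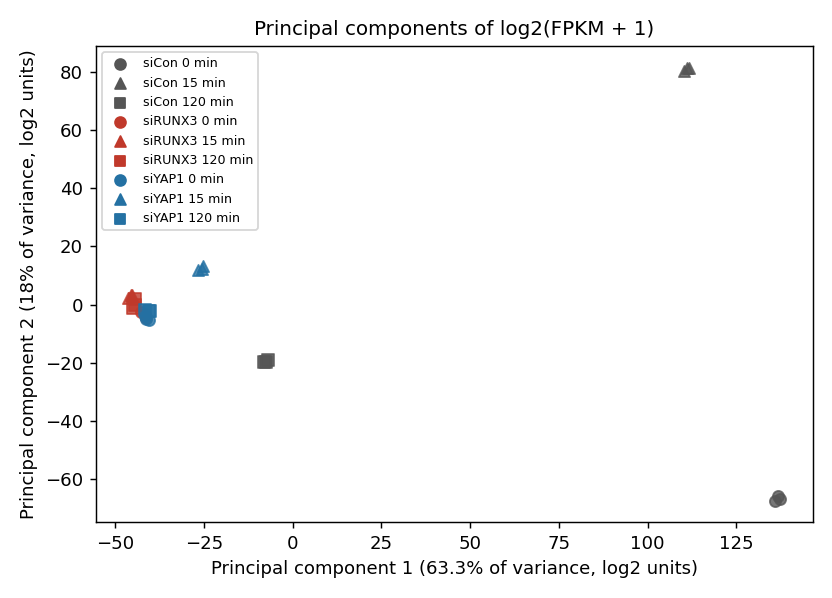
First and second principal components of log2(FPKM + 1) in the 27 libraries (63.3% and 18% of variance); colour gives the siRNA label and shape the time in min. The siCon libraries at 0 and 15 min lie away from the other 21.

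In siCon cells, the first planned comparison asked which transcripts differed 120 min after TGFb1 was added. It called 13114 of the 14543 tested genes (7340 higher, 5774 lower). The counts of list members called must be read beside that share. Of 20 genes known to respond to TGFb and SMAD proteins, 16 rose and 2 fell (18 called adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.073 with an estimated correlation). ID2, an inhibitor of differentiation, rose from 8.67 ± 1.7 to 54.2 ± 1.5 FPKM, the feedback inhibitor SMAD7 from 1.03 ± 0.46 to 9.52 ± 0.42 FPKM, and the AP-1 gene JUNB from 0.386 ± 0.42 to 6.55 ± 0.53 FPKM. BAMBI, a decoy receptor, was listed at 0 at 0 min and stood at 11.7 ± 0.46 FPKM at 120 min. Mitotic genes rose in 19 of 20 cases (20 called adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.085 with an estimated correlation), with CDK1, the mitotic kinase, at a log2 change of 2.53 ± 0.04 and the kinetochore motor CENPE at 2.27 ± 0.09. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail and which were listed as a marker of how RNA was selected for the libraries, fell in 14 of 17 cases (16 called adjusted over the list alone; camera adjusted p = 0.022, adjusted p = 0.085 with an estimated correlation), with HIST2H2AC going from 64.5 ± 7.3 to 3.6 ± 0.89 FPKM. RNA selection itself was not measured, and the level of these histone genes also depends on replication. The 7 tested markers of other cell types fell (7 called adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.073 with an estimated correlation), with LYZ going from 13.1 ± 1 to 0.202 ± 0.072 FPKM and HBA1 from 14.6 ± 2 to 0.388 ± 0.12 FPKM.

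Single genes changed by far more in siCon. The files hold no read counts, so a gene listed at 0 need not be absent. The largest rises by log2 change (pseudocount 1) from 0 to 120 min were mostly in genes that the siCon libraries at 0 min list at 0. At 120 min the mitochondrial iron-sulfur gene BOLA3 stood at 58.8 ± 5.4 FPKM, the endosomal sorting gene VPS25 at 54.5 ± 4.2 and FBXO22-AS1 at 39.9 ± 3.8. The complex I assembly gene TMEM126B stood at 36 ± 2.1, AK6 at 32.8 ± 0.56, CDKN3 at 26.7 ± 2.3 and ARV1 at 22.4 ± 0.83. The small nucleolar RNAs SNORA70, SNORA25, SNORA4 and SNORD97 were also listed at 0 at 0 min, and RPL21, a ribosomal protein gene used by every cell, went from 0.0274 ± 0.00026 to 34.2 ± 8.6 FPKM. The chemokine gene CCL5 fell from 833 ± 42 to 2.52 ± 0.28 FPKM, a log2 change of -7.89 ± 0.10 (limma adjusted p = 1.3e-26). LINC01133 fell from 99.1 ± 0.95 to 0.0354 ± 0.031 FPKM and NEXN-AS1 from 130 ± 6.9 to 0.517 ± 0.24 FPKM. SNORD26, SNORA43, SNORA47, SNORA48 and SNORA76A had means of 19300, 739, 649, 362 and 148 FPKM at 0 min and were listed at 0 at 120 min. At 15 min SNORD104, SNHG25, SNORD22, SNORA70 and RPL21 had risen, RPL21 to 731 ± 173 FPKM, while SNORD26, SNORA47, SNORA76A and RNU12 were listed at 0 and SNORA43 stood at a mean of 2.92 FPKM.

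At 15 min in siCon, stress genes were higher than at 0 min. Of 19 genes of the unfolded protein and integrated stress response, 16 rose and 2 fell (18 called adjusted over the list alone; camera adjusted p = 0.0011). XBP1, a transcription factor of that response, went from 6 ± 0.9 to 44.9 ± 0.79 FPKM, and DDIT3, a proapoptotic factor listed at 0 at 0 min, stood at 14.2 ± 1.9 FPKM. YAP and TEAD targets fell in 12 of 17 cases (16 called adjusted over the list alone; camera adjusted p = 0.02, adjusted p = 0.13 with an estimated correlation), with the tissue factor gene F3 going from 13 ± 2.2 to 1.26 ± 0.21 FPKM and PTPN14 from 18.3 ± 1.1 to 4.45 ± 0.052 FPKM. After quantile normalization the camera adjusted p of that list was 0.2. In all, 12917 genes were called at 15 min (7139 higher, 5778 lower) and 13114 at 120 min (7340 higher, 5774 lower), 6037 and 6342 of them by at least 2-fold. Each of these changes is measured against the siCon libraries at 0 min, which stand apart. The median log2 change of all tested genes was 0.142 at 15 min and 0.196 at 120 min, and 0.0249 and 0.236 after quantile normalization.

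In siRUNX3 cells the same comparison uses no siCon library as a reference. Genes of ribosome production and of the unfolded protein and integrated stress response were higher already at 15 min than at 0 min. Without libraries kept as long without TGFb1, an effect of TGFb1 cannot be told apart from a difference of the 0 min libraries. Of 20 ribosome biogenesis genes, 19 rose at 15 min (19 called adjusted over the list alone; camera adjusted p = 3.1e-12) and 20 at 120 min (20 called adjusted over the list alone; camera adjusted p = 1.2e-13). NIP7 went from 25.9 ± 0.56 to 51.4 ± 1.6 and 48.6 ± 1.4 FPKM and NOP16 from 63.5 ± 1.6 to 128 ± 6 and 111 ± 2.3 FPKM at 15 and 120 min. Of 19 genes of the unfolded protein and integrated stress response, 18 rose at 15 min (19 called adjusted over the list alone; camera adjusted p = 3.0e-08) and 17 at 120 min (18 called adjusted over the list alone; camera adjusted p = 3.7e-08). The endoplasmic reticulum chaperone HSPA5 went from 313 ± 1.4 to 558 ± 2 and 536 ± 0.99 FPKM and its cochaperone DNAJB9 from 16.2 ± 0.38 to 43.1 ± 1.9 and 41.7 ± 0.46 FPKM. VLDLR, a lipoprotein receptor in that list, fell, with log2 changes of -0.84 ± 0.07 and -0.81 ± 0.07.

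Mitotic genes also rose in siRUNX3, in 16 of 20 cases at 15 min (17 called adjusted over the list alone; camera adjusted p = 1.6e-06) and 16 at 120 min (16 called adjusted over the list alone; camera adjusted p = 3.8e-07). CDK1 changed by 0.76 ± 0.04 and 0.49 ± 0.04 on the log2 scale, and UBE2C, which passes ubiquitin to mitotic substrates, by 0.67 ± 0.04 and 0.62 ± 0.04. Of the 17 histone genes listed as a marker of RNA selection, 15 rose at 15 min (15 called adjusted over the list alone; camera adjusted p = 0.002) and 12 at 120 min (13 called adjusted over the list alone; camera adjusted p = 0.0078), with HIST2H2AC going from 3.09 ± 0.6 to 6.71 ± 0.84 and 9.36 ± 1.5 FPKM. E2F targets and replication genes rose in 19 of 22 cases at 15 min (20 called adjusted over the list alone; camera adjusted p = 2.0e-06) and 19 at 120 min (20 called adjusted over the list alone; camera adjusted p = 3.8e-07), led by the origin licensing gene CDC6, from 63.3 ± 1.1 to 121 ± 2 and 118 ± 1.5 FPKM. After quantile normalization 9 of them were higher and 5 lower at 15 min, with a median log2 change of -0.02 and a camera adjusted p of 0.66, and 0.059 at 120 min. Cytosolic ribosomal proteins rose in 24 of 24 cases at 15 min (24 called adjusted over the list alone; camera adjusted p = 3.5e-15) and 22 at 120 min (23 called adjusted over the list alone; camera adjusted p = 1.9e-08), by medians of 0.28 and 0.14. After quantile normalization those medians were 0.06 and 0.03, with camera adjusted p of 0.038 and 0.38.

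Matrix and sterol genes were lower in siRUNX3 after TGFb1. Of 22 genes of epithelial-mesenchymal transition and extracellular matrix, 16 fell at 15 min (18 called adjusted over the list alone; camera adjusted p = 6.2e-05) and 13 at 120 min (17 called adjusted over the list alone; camera adjusted p = 5.5e-04). The fibronectin receptor subunit ITGA5 went from 10.2 ± 0.76 to 4.41 ± 0.18 and 4.57 ± 0.4 FPKM and the collagen gene COL4A1 from 8.1 ± 0.18 to 4.46 ± 0.037 and 4.46 ± 0.24 FPKM. Cholesterol synthesis genes fell in 12 of 19 cases at 15 min (16 called adjusted over the list alone; camera adjusted p = 0.0078) and 12 at 120 min (15 called adjusted over the list alone; camera adjusted p = 0.0053). TGFb and SMAD response genes rose in 11 of 20 cases at 15 min (12 called adjusted over the list alone; camera adjusted p = 0.078), which missed the threshold as a list, and in 12 at 120 min (13 called adjusted over the list alone; camera adjusted p = 0.027). After quantile normalization the camera adjusted p at 15 min was 0.024. SMAD7 went from 4.54 ± 0.46 to 10.2 ± 0.63 and 9.48 ± 0.62 FPKM and ID1 from 20.2 ± 1.9 to 41.1 ± 0.55 and 37.1 ± 1.4 FPKM.

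Single genes of the siRUNX3 time course were chosen after their values were seen, with the counts of the siCon rule. MT1X, a metal-binding metallothionein, rose from 15.8 ± 2.3 to 102 ± 6.7 and 85.2 ± 6.1 FPKM at 15 and 120 min, and the stress transcription factor ATF5 from 3.28 ± 0.53 to 19.4 ± 1.6 and 19.3 ± 1.5 FPKM. The zinc exporter SLC30A1 rose from 9.1 ± 0.54 to 34.1 ± 0.56 FPKM at 120 min. HSPA1B, an inducible heat shock protein, fell from 219 ± 1.8 to 59 ± 0.88 and 59.4 ± 1.2 FPKM, and HILPDA, a lipid droplet protein induced by hypoxia, from 71.6 ± 2.3 to 18.9 ± 1.1 FPKM at 120 min. Other rises at 120 min were in AMIGO3 (1.99 ± 0.06), LANCL2 (1.49 ± 0.10), OSTN (1.48 ± 0.26), CGA (1.44 ± 0.20) and the small nucleolar RNAs SNORA16A, SNORA84, SNORA69 and SNORA81. The other falls were in SOSTDC1, MIR210HG, RAB3A, S1PR5, ZBTB7B and SLITRK3, with log2 changes between -1.61 and -1.36. At 15 min the named rises also held SNORA2A, SNORA70 and CGA (1.88 ± 0.20), and the falls SNORA8, S1PR5 (-1.83 ± 0.09), SOSTDC1 (-1.67 ± 0.16) and MIR210HG (-1.61 ± 0.12). The calls of SNORA69, SNORA81 and SNORA84 at 120 min and of SNORA70 and SNORA8 at 15 min were each lost in at least 1 alternative or without 1 library, with adjusted p up to 0.14 and 0.27.

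The siRUNX3 changes at both times were alike. Of 152 genes changed at least 2-fold at 15 min and 118 at 120 min, 94 were shared in the same direction, among them MT1X and HSPA1B. Independent sets would share 0.377 higher and 0.246 lower genes. Both sets use the same libraries at 0 min, and part of the overlap may come from them. In 20 simulated sets with these shared libraries and no true change, no gene was called at both times in the same direction. These sets hold only the spread within groups, so they cannot show the effect of a shift common to the 3 libraries at 0 min. Across all tested genes the covariance of the 2 log2 changes was 0.122, against 0.0152 in the simulated sets. In all, 8457 genes were called at 15 min (4499 higher, 3958 lower) and 7633 at 120 min (4075 higher, 3558 lower). After quantile normalization fewer were higher than lower, 3266 against 3593 at 15 min and 3114 against 3368 at 120 min. Between 15 and 120 min 1338 genes were called (501 higher, 837 lower) in a contrast added after the data were seen, and 694 after quantile normalization (533 higher, 161 lower). Ribosomal protein genes fell there in 22 of 24 cases (23 called adjusted over the list alone; camera adjusted p = 9.9e-41), but after quantile normalization in 3 with 1 higher; RPL34 changed by -0.23 ± 0.03.

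In siYAP1 cells fewer genes changed at least 2-fold than in siRUNX3 cells, 14 against 152 at 15 min. The counts depended on the processing, with 67 against 522 at a pseudocount of 0.1 and 19 against 97 after quantile normalization. The siYAP1 libraries at 15 min leaned toward the siCon libraries of that time: across genes, the change from 0 to 15 min correlated at 0.66 with the difference of siCon at 15 min from siYAP1 at 0 min, which share the siYAP1 libraries at 0 min. At 15 min ribosome biogenesis genes rose in 13 of 20 cases and fell in 3 (16 called adjusted over the list alone; camera adjusted p = 2.7e-05), and the camera adjusted p was 0.14 after quantile normalization. RRP9 rose from 29 ± 1.4 to 46 ± 1 FPKM and PPAN from 52.1 ± 2.8 to 79.8 ± 1.6 FPKM. Cholesterol synthesis genes fell in 11 of 19 cases and rose in 5 (17 called adjusted over the list alone; camera adjusted p = 0.015), with the sterol sensor INSIG1 going from 87 ± 0.56 to 57.9 ± 1.4 FPKM. Immediate early genes rose in 13 of 24 cases (17 called adjusted over the list alone; camera adjusted p = 0.046, adjusted p = 0.082 with an estimated correlation); the growth factor induced gene EGR1 went from 1.53 ± 0.25 to 3.12 ± 0.18 and 2.96 ± 0.3 FPKM at 15 and 120 min and IER2 from 27.5 ± 0.76 to 42.5 ± 1.6 FPKM at 15 min. At 120 min that list rose in 5 cases (5 called adjusted over the list alone; camera adjusted p = 0.0066).

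At 120 min in siYAP1, ribosome biogenesis genes rose in 15 of 20 cases (17 called adjusted over the list alone; camera adjusted p = 5.6e-12), by a median of 0.13. Heat shock proteins rose in 7 of 13 cases (9 called adjusted over the list alone; camera adjusted p = 2.5e-07), with HSPA1B going from 185 ± 4.6 to 220 ± 1.8 FPKM. Matrix genes fell in 9 of 22 cases (11 called adjusted over the list alone; camera adjusted p = 1.8e-06), with FN1, which encodes fibronectin, going from 7.84 ± 0.33 to 6.11 ± 0.11 FPKM. The histone genes that mark RNA selection rose in 5 of 17 cases (7 called adjusted over the list alone; camera adjusted p = 0.0044), with HIST1H4C going from 3.69 ± 1 to 7.22 ± 0.45 FPKM. Hypoxia response genes fell in 4 of 18 cases (4 called adjusted over the list alone; camera adjusted p = 0.021), with P4HA1 at -0.25 ± 0.05. BCL2 family genes, which control apoptosis, rose in 4 of 16 cases (5 called adjusted over the list alone; camera adjusted p = 0.018). TGFb and SMAD response genes were not called as a list (camera adjusted p = 0.86), while ID1 rose from 17.1 ± 0.51 to 23 ± 2.1 FPKM.

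Single genes of the siYAP1 time course, chosen after their values were seen, were less stable. Of 20 at 120 min, 6 kept their call under every alternative and without any single library. These were the histone genes HIST1H4C and HIST1H3B (0.58 ± 0.11), EGR1, LINC01355 (-0.68 ± 0.07), the ribonuclease gene RNASE4 (-0.65 ± 0.10) and the protease gene HTRA3 (-0.50 ± 0.10). The other 14 lost their call at least once, with adjusted p up to 0.25: SNORA81, URGCP-MRPS24, TGIF2-C20orf24, P2RY11, PRKAG2-AS1, UNC5B-AS1, HIST1H2AI, NME1-NME2 and HIST1H4E, which were higher, and S100A4, MIR4435-2HG, SPINT1, LOC100129917 and LINC01021, which were lower. At 15 min 6 of 9 followed here kept their call: IPO11-LRRC70, KRTAP19-1, LOC101930071 and P2RY11 rose, and BIVM-ERCC5 and SLMO2-ATP5E fell. EIF4EBP3, which was higher, and SNORA18 and SNORD17, which were lower, lost it at least once, with adjusted p up to 0.14. In all, 6808 genes were called at 15 min (3547 higher, 3261 lower) and 1912 at 120 min (1154 higher, 758 lower). After quantile normalization 3211 were higher and 3323 lower at 15 min, and 529 higher and 887 lower at 120 min. Without siYAP1 replicate 2 at 0 min 1273 were called at 120 min, and 3377 without the siCon libraries at 0 and 15 min. YAP and TEAD targets were not called as a list in the time course of siRUNX3 or siYAP1.

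**Figure D3:**
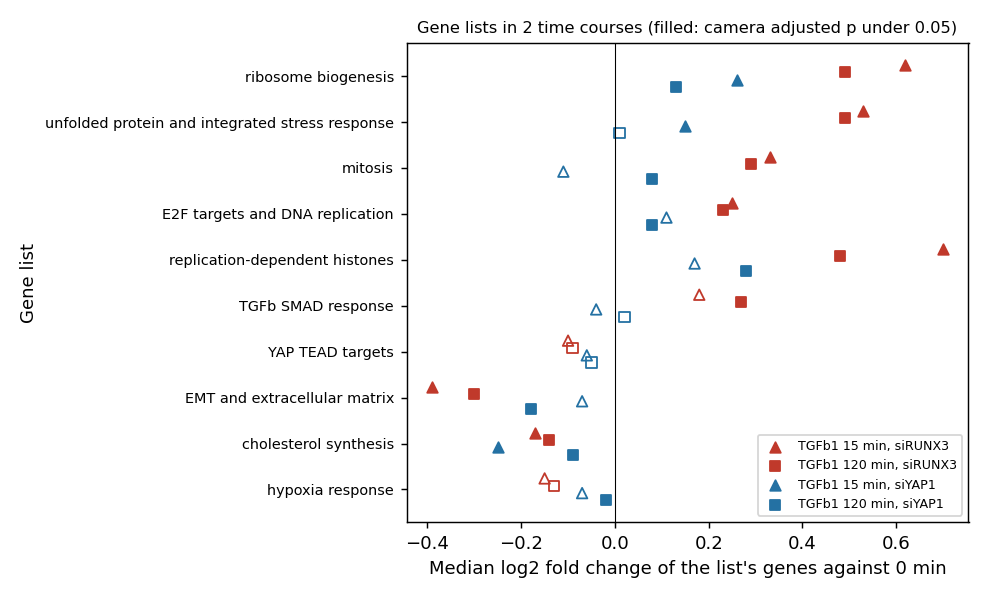
Median log2 fold change against 0 min (horizontal axis) of 10 gene lists (vertical axis) in siRUNX3 (red) and siYAP1 (blue) at 15 min (triangles) and 120 min (squares); filled symbols had a camera adjusted p under 0.05. Ribosome biogenesis lay at 0.62 and 0.49 in siRUNX3 and at 0.26 and 0.13 in siYAP1; after quantile normalization its call at 15 min in siYAP1 was lost.

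The comparison of siRUNX3 with siCon asked which transcripts differed under the RUNX3 siRNA at each time. ATF3, a stress-induced transcription factor, stood at 69.7 ± 0.42, 110 ± 2.5 and 93.2 ± 1.2 FPKM in siRUNX3 at 0, 15 and 120 min and at 3.43 ± 0.39, 4.96 ± 1.1 and 6.65 ± 0.64 in siCon. The endoplasmic reticulum stress gene HERPUD1 was higher in siRUNX3 by 5.60 ± 0.11, 3.93 ± 0.11 and 3.13 ± 0.11 on the log2 scale, the mTORC1 inhibitor DDIT4 by 3.10 ± 0.07, 2.63 ± 0.07 and 2.49 ± 0.07, and the growth arrest gene GADD45A by 2.46 ± 0.10, 3.66 ± 0.10 and 2.87 ± 0.10. CTH, SNORA40, TVP23C-CDRT4, OSTN, IFRD1 and TNFRSF12A were also higher at all 3 times. The tumour suppressor HIC1 was lower, at 5.95 ± 0.75, 4.92 ± 1.2 and 5.6 ± 1.5 FPKM in siRUNX3 and 394 ± 105, 115 ± 28 and 20.7 ± 6 in siCon. NF2, the Hippo pathway regulator merlin, was lower, at 9.11 ± 1.2, 7.48 ± 0.78 and 9.57 ± 0.4 FPKM against 24.1 ± 1.7, 42.7 ± 1.8 and 23.2 ± 0.29. C8orf49, SHC3, FOXK1, LOC441081, BMP8B, KCNJ14, LOC100272216 and GATSL2 were also lower at all 3 times. The call of SNORA40 at 120 min was lost after quantile normalization (adjusted p = 0.07), in the model with only the groups compared (0.23) and without siCon replicate 1 at 120 min (0.1). After the length and GC correction GATSL2 differed by -0.029 at 0 min (adjusted p = 0.66) and by 0.231 at 15 min (0.0016), the other direction. In all, 5618 genes were higher and 289 lower at all 3 times. At 0 and 15 min these differences are against the siCon libraries that stand apart. The median log2 difference of all tested genes was 0.624 at 0 min and 0.353 at 15 min, and 0.186 and 0.0344 after quantile normalization.

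At 120 min siCon correlated with the siRUNX3 and siYAP1 groups at means of 0.9569 to 0.9696, and those groups with each other at 0.9704 to 0.9881. A difference of the siCon libraries themselves thus cannot be told apart from an effect common to both siRNAs. The median log2 difference of all tested genes between siRUNX3 and siCon at 120 min was 0.444, and -8.65e-05 after quantile normalization. The gene lists are compared with all other genes, so relative to that median. All 19 unfolded protein and integrated stress response genes were higher (19 called adjusted over the list alone; camera adjusted p = 2.5e-09), and 15 were higher and 3 lower after quantile normalization. CHAC1, which degrades glutathione, stood at 24.4 ± 0.47 against 0.923 ± 0.22 FPKM and DDIT3 at 59.5 ± 3.3 against 4.6 ± 0.34 FPKM. Hypoxia response genes were higher in 18 of 18 cases (18 called adjusted over the list alone; camera adjusted p = 5.5e-05), and 16 were higher and 1 lower after quantile normalization, with the angiogenic factor VEGFA at 53 ± 0.46 against 7.55 ± 0.24 FPKM and the mitophagy gene BNIP3 at 129 ± 3.1 against 27.7 ± 1 FPKM. Immediate early genes were higher in 24 of 24 cases (24 called adjusted over the list alone; camera adjusted p = 1.8e-04), and 21 were higher and 1 lower after quantile normalization, with JUN at 212 ± 3.8 against 43 ± 1.8 FPKM. Targets of p53 were higher in 19 of 20 cases (20 called adjusted over the list alone; camera adjusted p = 0.0049), and 14 were higher and 1 lower after quantile normalization, with the cell cycle inhibitor CDKN1A at 29 ± 0.83 against 4.27 ± 0.35 FPKM. Cholesterol synthesis genes were higher in 18 of 19 cases (19 called adjusted over the list alone; camera adjusted p = 6.4e-05), and 16 were higher and 3 lower after quantile normalization, with the isoprenoid enzyme IDI1 at 112 ± 4.1 against 22.9 ± 1.1 FPKM.

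The 24 cytosolic ribosomal protein genes were higher in siRUNX3 at 120 min (24 called adjusted over the list alone; camera adjusted p = 2.8e-15), but 12 were higher and 9 lower after quantile normalization (camera adjusted p = 0.46), with RPS27 at 1.75 ± 0.04. Hippo pathway genes were higher in 13 of 24 cases and lower in 5 (18 called adjusted over the list alone; camera adjusted p = 0.04). Their median log2 difference was 0.31, under that of all genes, so camera placed the list lower than other genes, and its adjusted p was 0.31 after the length and GC correction. LATS1, a Hippo kinase, stood at 18.9 ± 0.73 against 8.98 ± 0.2 FPKM. YAP and TEAD targets were not called as a list (camera adjusted p = 0.21), though its member CYR61 was higher, at 15.7 ± 0.94 against 5.13 ± 0.29 FPKM. Between siRUNX3 and siCon, 13472 genes were called at 0 min (9071 higher, 4401 lower), 12781 at 15 min (7887 higher, 4894 lower) and 10985 at 120 min (10125 higher, 860 lower). At least 2-fold differences numbered 8070, 7394 and 1558. After quantile normalization 4095 were higher and 4367 lower at 120 min, and 373 differed at least 2-fold.

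In siYAP1 against siCon, ATF3 was higher by 3.78 ± 0.08, 3.46 ± 0.08 and 3.13 ± 0.08 on the log2 scale at 0, 15 and 120 min, DDIT4 by 3.01 ± 0.07, 3.04 ± 0.07 and 2.85 ± 0.07, and VEGFA by 2.34 ± 0.04, 2.85 ± 0.04 and 2.61 ± 0.04. JUN was higher by 2.63 ± 0.05, 2.94 ± 0.05 and 2.39 ± 0.05, and INSIG1 by 2.71 ± 0.04, 2.26 ± 0.04 and 2.40 ± 0.04. CTH, MIR210HG, ARRDC4, GADD45A and BNIP3 were also higher at all 3 times. ATF5 was lower, at 3.09 ± 0.44, 4.97 ± 0.52 and 3.46 ± 0.11 FPKM in siYAP1 and 24.4 ± 2, 81.5 ± 2.9 and 16.3 ± 1.1 in siCon. HIC1, SHC3, C8orf49, NF2, IBA57, HIST1H2AD, FOXK1, SNRNP35 and PRKAR1B were also lower at all 3 times. After the length and GC correction HIST1H2AD differed by 0.270 at 15 min (adjusted p = 0.22). In all, 5791 genes were higher and 316 lower at all 3 times, at 0 and 15 min against the siCon libraries that stand apart. The median log2 difference of all tested genes was 0.617 at 0 min and 0.402 at 15 min, and 0.184 and 0.0337 after quantile normalization.

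At 120 min that median between siYAP1 and siCon was 0.448, and -0.0045 after quantile normalization. Hypoxia response genes were higher in 18 of 18 cases (18 called adjusted over the list alone; camera adjusted p = 3.2e-06), and 17 were higher after quantile normalization, with ENO2, a glycolytic enzyme, at 27.7 ± 1.1 against 5.31 ± 0.42 FPKM. Unfolded protein and integrated stress response genes were higher in 17 of 19 cases (17 called adjusted over the list alone; camera adjusted p = 6.0e-06), and 15 were higher and 4 lower after quantile normalization, with CHAC1 at 18 ± 0.38 against 0.923 ± 0.22 FPKM and DDIT3 at 51.1 ± 1.1 against 4.6 ± 0.34 FPKM. Targets of p53 were higher in 19 of 20 cases (20 called adjusted over the list alone; camera adjusted p = 4.9e-04), and 16 were higher and 2 lower after quantile normalization, with the proapoptotic gene BBC3 at 20.2 ± 0.73 against 3.69 ± 0.43 FPKM. Cholesterol synthesis genes were higher in 18 of 19 cases (19 called adjusted over the list alone; camera adjusted p = 2.8e-05), and 17 were higher and 2 lower after quantile normalization, with MSMO1 at 35.8 ± 2 against 10.2 ± 0.35 FPKM. The histone genes that mark RNA selection were lower in 13 of 17 cases (13 called adjusted over the list alone; camera adjusted p = 3.9e-12), and in 17 after quantile normalization, with HIST1H2BC at 11.1 ± 1.7 against 22.6 ± 3.7 FPKM.

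Actin cytoskeleton genes were higher in 11 of 20 cases and lower in 6 in siYAP1 at 120 min (17 called adjusted over the list alone; camera adjusted p = 0.0037, adjusted p = 0.077 with an estimated correlation). Their median log2 difference was 0.15, under that of all genes, so camera placed them lower, and 3 were higher and 17 lower after quantile normalization. ACTB, cytoplasmic beta actin, stood at 777 ± 5 against 1316 ± 9 FPKM. YAP and TEAD targets were not called as a list (camera adjusted p = 0.54), though CYR61, a matricellular YAP target, was higher at 9.91 ± 0.17 against 5.13 ± 0.29 FPKM. Between siYAP1 and siCon, 13480 genes were called at 0 min (9100 higher, 4380 lower), 12663 at 15 min (8171 higher, 4492 lower) and 11436 at 120 min (10486 higher, 950 lower). At least 2-fold differences numbered 8037, 6670 and 1645. After quantile normalization 4415 were higher and 4766 lower at 120 min, and 598 differed at least 2-fold.

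The siRUNX3 and siYAP1 groups shared most of their differences from siCon. At 120 min 9067 genes were higher and 442 lower in both, among them ATF3, CHAC1, VEGFA and NF2, and 402 were called in opposite directions. At 0 min 8866 were higher and 4226 lower in both, and at 15 min 7403 and 4166. Both comparisons use the same 3 siCon libraries at each time. In 20 simulated sets with that shared control and no true difference, at most 1 gene was called in both in the same direction at any of the 3 times. The simulated sets hold only the spread within groups, so they cannot show the effect of a shift common to the 3 siCon libraries. Independent lists would share 7300 higher and 56 lower genes at 120 min. Part of the excess may come from the shared siCon libraries. After quantile normalization 2944 were higher and 3328 lower in both at 120 min.

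The interaction asked whether the TGFb1 change differed between siRUNX3 or siYAP1 and siCon. CCL5 stood at 2.72 ± 0.45 FPKM at 0 min and 2.17 ± 0.15 at 120 min in siRUNX3, and at 2.51 ± 0.29 and 2.88 ± 0.34 in siYAP1, while it fell from 833 to 2.52 FPKM in siCon. Its log2 interactions were 7.67 ± 0.14 in siRUNX3 and 8.04 ± 0.14 in siYAP1, with limma adjusted p of 4.1e-23 and 1.7e-23. The other genes named by the rule were small nucleolar RNAs, such as SNORA43, at 739 FPKM in siCon at 0 min and listed at 0 in siCon at 120 min and in siRUNX3 and siYAP1 at 0 and 120 min. At 120 min TGFb and SMAD response genes had lower interactions in 15 of 20 cases in siRUNX3 (17 called adjusted over the list alone; camera adjusted p = 0.032, adjusted p = 0.071 with an estimated correlation) and 17 in siYAP1 (19 called adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.054 with an estimated correlation). BAMBI, JUNB and ID2 had the lowest of these in siRUNX3, at -3.38 ± 0.08, -2.62 ± 0.18 and -2.12 ± 0.10. The histone genes that mark RNA selection had higher interactions in 15 of 17 cases in siRUNX3 (16 called adjusted over the list alone; camera adjusted p = 0.017, adjusted p = 0.056 with an estimated correlation) and 14 in siYAP1 (16 called adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.054 with an estimated correlation). Each interaction contains the siCon libraries at 0 min that stand apart. In siRUNX3 12297 genes were called at 15 min (5459 higher, 6838 lower) and 12492 at 120 min (5572 higher, 6920 lower). In siYAP1 11972 were called at 15 min (5143 higher, 6829 lower) and 12514 at 120 min (5531 higher, 6983 lower).

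The siRUNX3 and siYAP1 groups were also compared directly, in contrasts chosen after the data were seen that leave siCon out. At 0 min siRUNX3 and siYAP1 differed in 2429 genes (1533 higher and 896 lower in siRUNX3; 794 and 1029 after quantile normalization), 9 of them by at least 2-fold, and in 3802 genes in the model without the siCon libraries at 0 and 15 min. Heat shock proteins were higher in siRUNX3 in 9 of 13 cases (10 called adjusted over the list alone; camera adjusted p = 1.6e-09), but 3 were higher and 1 lower after quantile normalization, with DNAJB1 at 76.5 ± 1.3 against 61.1 ± 0.8 FPKM. At 15 min, where siYAP1 leaned toward siCon, 9405 genes differed (394 by at least 2-fold) and at 120 min 7892 (123 by at least 2-fold). At 120 min ribosome biogenesis genes were higher in siRUNX3 in 20 of 20 cases (20 called adjusted over the list alone; camera adjusted p = 5.5e-13) and unfolded protein and integrated stress response genes in 18 of 19 cases (19 called adjusted over the list alone; camera adjusted p = 3.5e-10). HSPA5 stood at 536 ± 0.99 against 276 ± 3.1 FPKM, CDC6 at 118 ± 1.5 against 57.9 ± 1.5 FPKM and ITGA5, which was lower, at 4.57 ± 0.4 against 9.73 ± 0.2 FPKM.

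The TGFb1 change itself differed between siRUNX3 and siYAP1 in 7074 genes at 15 min and 4743 at 120 min. The siRUNX3 libraries at 0 min correlated more closely with siYAP1 at 0 and 120 min (mean 0.9858 and 0.9855) than with siRUNX3 at 15 and 120 min (0.9768 and 0.9777). A different TGFb1 change thus cannot be told apart from a difference in preparation or label of the siRUNX3 libraries at 15 and 120 min. At 120 min ribosome biogenesis genes had a larger change in siRUNX3 in 17 of 20 cases (19 called adjusted over the list alone; camera adjusted p = 2.5e-13), with NIP7 at a log2 difference of 0.76 ± 0.07, and TGFb and SMAD response genes in 9 of 20 cases (9 called adjusted over the list alone; camera adjusted p = 0.033, adjusted p = 0.071 with an estimated correlation), with SMAD7 at 0.93 ± 0.15. Heat shock proteins had a lower change in 7 of 13 cases and a larger in 3 (11 called adjusted over the list alone; camera adjusted p = 0.0035, adjusted p = 0.079 with an estimated correlation), with HSPA1B at -2.11 ± 0.03. Between 15 and 120 min in siYAP1 6167 genes were called (3069 higher, 3098 lower), and 3493 after the length and GC correction. There mitotic genes rose in 14 of 20 cases and fell in 4 (18 called adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.22 with an estimated correlation), with the kinesin KIF20A at 0.46 ± 0.06 and BIRC5, an inhibitor of apoptosis active in mitosis, at -0.34 ± 0.02.

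Over the 16 planned contrasts 384 pairs of list and contrast were tested. Camera called 124 with the preset correlation and 82 with an estimated one, and 42 of the calls were lost there.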

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

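In this part, the test of few molecules sampled, the ratio of corrected to uncorrected changes, the direct tests of siRUNX3 against siYAP1, the splits of the contrasts added later and the splits of the same-direction calls were chosen only after the result was seen.

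The change after TGFb1 differed between groups by a test of the difference itself. At 120 min the siRUNX3 interactions singled out by the naming rule were SNORA84 (10.60), SNORD26 (10.27), SNORA43 (9.53), SNORA47 (9.18), CCL5 (7.67), SNORD97 (-7.63), SNORA76A (7.14) and SNORA48 (7.06) on the log2 scale. Those of siYAP1 were SNORD26 (14.23), SNORA43 (9.53), SNORA48 (8.59), CCL5 (8.04), SNORA4 (-7.21), SNORA76A (7.14), SNORA47 (6.70) and SNORA57 (6.70). Apart from CCL5, a chemokine gene, these are small nucleolar RNAs; where libraries are listed at 0, the values depend on the pseudocount and are no folds. Some rest on single libraries: SNORD26 in siRUNX3 at 0 min was listed at 0 in 2 libraries and stood at 3730 FPKM in the other. Interactions were called in 12297 genes in siRUNX3 at 15 min and 12492 at 120 min, and in 11972 and 12514 in siYAP1. Of 100 splits, 2 and 2 were as large for siRUNX3, with 13688 and 13372 as the highest others, each a full exchange of the labels at 1 time. For siYAP1 that full exchange was not among the splits drawn. There 1 and 1 were as large, and the highest others were 11438 and 12129. Splits that kept the real groups at 0 min alone reached 11190 and 12182 for siRUNX3 and 11438 and 12129 for siYAP1, while those that mixed them at both times reached at most 1. Splits that mix separated groups lose nearly all calls, so the outcome was set by how these libraries part, siCon from the others. The splits thus give no support against chance of their own. They cannot exclude a chance difference between cultures or preparations, since the 3 libraries of a group may be repeat measurements. On the interaction itself they have no bearing. The change also differed between siRUNX3 and siYAP1 in 7074 genes at 15 min and 4743 at 120 min. There 10 of 100 splits were as large at each time, the highest others giving 8584 and 7401 genes; beside the real split, the 9 as large all kept the real groups at the later time, so this share has no bearing on chance. Of the genes named for the siRUNX3 time course, 8 of 10 at 15 min and 17 of 20 at 120 min, MT1X, ATF5 and HSPA1B among them, differed in their change from siYAP1; of those named for siYAP1, 6 of 10 and 6 of 20 did.

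The genes called in the same direction in siRUNX3 and siYAP1 against siCon numbered 13092 at 0 min, 11569 at 15 min and 9509 at 120 min. Of 100 splits, 2, 2 and 1 were as large, with 13182, 11723 and 0 as the highest others. At 0 and 15 min the other split as large kept the real siCon libraries together, splits that mixed siCon reached at most 1315 and 3028, and at 120 min no other split drawn kept siCon together. Here too the outcome was set by how these libraries part, siCon from the others. The splits thus give no support against chance, also not against a chance difference between cultures or preparations. They have no bearing on what siRUNX3 and siYAP1 share. For each comparison of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and 1 of 10, the real one, was as large. The real and highest other counts were 12917 and 7 in siCon at 15 min and 13114 and 0 at 120 min. They were 8457 and 1, and 7633 and 0, in siRUNX3, and 6808 and 2, and 1912 and 1, in siYAP1. For siRUNX3 against siCon at 0, 15 and 120 min they were 13472 and 0, 12781 and 1, and 10985 and 1, and for siYAP1 against siCon 13480 and 0, 12663 and 0, and 11436 and 0. For siRUNX3 against siYAP1 they were 2429 and 1, 9405 and 1, and 7892 and 1. Between 15 and 120 min they were 1338 and 1 in siRUNX3 and 6167 and 3 in siYAP1.

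The siCon libraries at 0 min stood apart from the siRUNX3 and siYAP1 libraries of that time. After removal of a trend in transcript length and GC content their mean correlation with those libraries across genes was 0.745, against 0.72 before, which argues against that trend as the whole cause. Over 792 abundant genes the SD of the log2 difference was 1.56, against a median SD of 0.0605 within the siCon libraries at 0 min. This argues against noise from few molecules sampled anew in each library. If the 3 libraries are repeat measurements of the same RNA, they would share an earlier loss of molecules, which the test cannot exclude. The correlation of the siCon change from 0 to 120 min with that of siRUNX3 was 0.125, and with that of siYAP1 -0.00764. Both lie under the bound set beforehand, but that bound assumes that siRUNX3 and siYAP1 cells respond like control cells. As seen only after, the changes of siRUNX3 and siYAP1 correlate with each other at only 0.213. For the siCon change from 0 to 120 min, these correlations thus cannot tell a response to TGFb1 apart from a difference of these libraries. At 15 min, 2692 genes were already at least 2-fold lower than at 0 min in siCon, and 2454 after quantile normalization. So many falls of that size within 15 min argue against a TGFb1 response as the whole cause of the siCon change at 15 min. At 0 min itself, with 0 min of TGFb1 in all groups, siCon differed from siRUNX3 in 13472 genes and from siYAP1 in 13480. This argues against a TGFb1 response as the cause of the parting at 0 min. A different origin, label or RNA selection of these libraries stays open beside a biological difference of the control cells: from 0 to 120 min in siCon 14 of 17 histone genes that mark RNA selection fell (camera adjusted p = 0.022, adjusted p = 0.085 with an estimated correlation), as did 7 of 7 markers of other cell types (0.021 and 0.073), and these values do not decide between them.

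In siRUNX3 the libraries at 15 and 120 min differed from those at 0 min in the same genes, among them MT1X, ATF5 and HSPA1B. Over the 118 genes changed at least 2-fold at 120 min, the siYAP1 change had a slope of 0.114 (SE 0.0236, genes taken as independent) on that of siRUNX3. This argues against a response to TGFb1 or to the change of medium of like size in siRUNX3 and siYAP1. A weaker shared response stays open, since 72% of these genes changed in the same direction in both (r = 0.408). The correlation across genes with the difference of siCon at 15 min from siRUNX3 at 0 min was 0.103 for the change at 15 min, which argues against an admixture of siCon RNA at that time; at 120 min admixture was not tested. After the length and GC correction 73.5% of 151 genes changed at least 2-fold at 15 min stayed so, 150 of the 151 kept an adjusted p under 0.05, and the corrected change had a median ratio of 0.958 to the uncorrected one (quartiles 0.916 and 1.03), which argues against that trend as the whole cause; as a small part it cannot be told apart, because the 73.5% lies between the bounds set for and against it. A TGFb1 response specific to siRUNX3 cells stays open and was not tested. So does a difference in preparation, label or RNA selection between the libraries at 0 min and those at 15 and 120 min. The histone markers of RNA selection rose in 15 of 17 cases at 15 min. These histone genes also depend on replication, and replication genes rose as well at 15 min, though not after quantile normalization. The histone rise thus does not single out RNA selection.

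The siYAP1 libraries at 15 min leaned toward the siCon libraries of that time. A share of 4.3% siCon RNA, estimated from 330 genes at least 8-fold higher in siCon at 15 min, would allow the 476 genes at least 8-fold lower there to change by -0.0635; they changed by a median of -0.355, an excess fall of 0.291 on the log2 scale, which argues against admixture alone. The correlation across genes of the siYAP1 change with that difference was 0.66 before the length and GC correction and 0.514 after it, which argues against that trend as the whole cause. A biological change that siYAP1 and control cells share 15 min after TGFb1 stays open, as does a preparation step shared by these libraries.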

How the results depend on the processing

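In this part the model without the siCon libraries at 0 and 15 min, the length and GC correction and the quantile normalization of the contrasts added later were chosen only after the result was seen. Of 345 counts of called genes or lists under an alternative or without 1 library, 336 stayed within 1.5 times the count reported. These counts are totals and do not track direction. For siRUNX3 against siCon at 120 min, 10125 higher and 860 lower became 4095 and 4367 after quantile normalization, within that bound. Counts of at least 2-fold changes were not in the tally. With a pseudocount of 0.1 those at 15 against 0 min went from 152 to 522 in siRUNX3 and from 14 to 67 in siYAP1. Of 4412 results of named genes, 4318 kept their direction and their side of the threshold, 86 lost their call, 3 gained one and 5 changed sign. The replicate block changed none of 337 gene results and left 122 list calls, against 124. Sign changes against siCon were, in log2: after quantile normalization, YAP1 in siYAP1 (-0.50) and MT1X in siRUNX3 (-0.124) at 120 min; after the length and GC correction, YAP1 in siRUNX3 at 120 min (0.045), HIST1H2AD in siYAP1 (0.270) and GATSL2 in siRUNX3 (0.231) at 15 min. Without the siCon libraries at 0 and 15 min, 3377 genes were called in siYAP1 at 120 against 0 min, 3802 in siRUNX3 against siYAP1 at 0 min and 2642 in siRUNX3 at 120 against 15 min. With all 9 groups 1912 genes were called in siYAP1 at 120 against 0 min; leaving out 1 library of the groups compared, this ranged from 1273, without siYAP1 replicate 2 at 0 min, to 1406, without siYAP1 replicate 2 at 120 min. Between 15 and 120 min, 694 genes were called in siRUNX3 after quantile normalization, and 623 in siRUNX3 and 3493 in siYAP1 after the length and GC correction. With an estimated correlation 82 list calls were made. Same-direction calls of siRUNX3 and siYAP1 at 120 min numbered 6272 after quantile normalization. The cause of these shifts was not tested; read depth is unknown, so what it limits could not be measured.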

Other observations

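Every gene in this part was chosen only after the result was seen. In siRUNX3 the metallothioneins MT1X and MT2A changed after TGFb1 by 2.63 ± 0.14 and 1.33 ± 0.17 on the log2 scale at 15 min and by 2.36 ± 0.14 and 1.19 ± 0.17 at 120 min, and the zinc exporter SLC30A1 by 1.60 ± 0.08 and 1.80 ± 0.08. The change was larger in siRUNX3 than in siYAP1 for each of them at 120 min, by 2.67 ± 0.20, 1.06 ± 0.24 and 1.84 ± 0.12, with limma adjusted p of 1.2e-09, 0.0019 and 5.9e-11. Against siCon at 120 min, siRUNX3 differed by 0.60 ± 0.14, 0.88 ± 0.17 and 2.18 ± 0.08, and by -0.12, 0.14 and 1.68 after quantile normalization. MT1F rose by 1.71 ± 0.33 at 15 min, and at 120 min its difference from siYAP1 missed the threshold (limma adjusted p = 0.13), but passed it without siRUNX3 replicate 2 at 0 min (0.034) or without siYAP1 replicate 3 at 120 min (0.047).

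TXNIP, an inhibitor of thioredoxin that responds to glucose, fell in siRUNX3 from 13.4 ± 0.6 to 5.13 ± 0.44 and 4.88 ± 0.16 FPKM at 15 and 120 min, and the glycolysis regulator PFKFB4 from 12.6 ± 0.41 to 5.52 ± 0.73 and 5.79 ± 0.2 FPKM. TGFBR2, a TGFb receptor kinase, fell from 2.46 ± 0.28 to 0.96 ± 0.044 and 1.22 ± 0.2 FPKM and TGFBR3, a coreceptor, from 6.88 ± 0.19 to 3.18 ± 0.25 and 3.68 ± 0.2 FPKM. The receptor-regulated SMAD gene SMAD3 fell from 6.35 ± 0.5 to 3.65 ± 0.3 and 4.13 ± 0.31 FPKM, while its partner SMAD4 rose from 5.67 ± 0.3 to 7.83 ± 0.28 and 7.74 ± 0.13 FPKM. The Hippo kinase LATS1 rose from 9.75 ± 0.3 to 17.6 ± 0.55 and 18.9 ± 0.73 FPKM. At 120 min the change in siRUNX3 differed from that in siYAP1 by -1.28 ± 0.09 for TXNIP, -0.55 ± 0.12 for TGFBR2, -0.52 ± 0.11 for SMAD3, 0.37 ± 0.07 for SMAD4 and 0.92 ± 0.12 for LATS1.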
